A study of Sus scrofa with 4 samples.

How the data were processed

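The series holds 4 RNA-seq libraries of parthenogenetic porcine 4-cell embryos, 2 treated with Bobcat339 and 2 given DMSO. Per the labels, total RNA was extracted with TRIzol and libraries were made with the Smart-seq2 system, which amplifies full-length cDNA and does not mark the strand. The number of embryos per library is not given in the sources used here. Samples were grouped by their titles and the treatment label. The labels give the DMSO dose in the unit of the inhibitor, and DMSO is treated here as the solvent control.

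The authors deposited raw read counts per gene, whole numbers that sum to a different total in each library. The submitters' processing notes name Trimmomatic, HISAT2 2.0.5, HTSeq and DESeq2 1.16.1, without their roles, and the genome build Sscrofa10.2. The deposited coordinates do not follow that build: of 14169 symbols that could be compared, 98.8% overlap the gene of that name in the Sscrofa11.1 annotation, so coordinates are given as in the table and named Sscrofa11.1. The authors also deposited FPKM values for each library, per the file headers, which are normalised by gene length and depth and were not tested. The table gives a length for each gene, deposited by the authors with no statement of how it was measured, and it was used only to check for a trend with length. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart, and near-identical copies such as ribosomal protein, metallothionein or mitochondrial pseudogenes may share counts.

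The table has 35248 rows, 25880 with an Ensembl identifier and 9368 loci with an XLOC identifier, and 5241 rows have 0 counts in all 4 libraries. Symbols came from the table (17600 rows), from an Ensembl identifier table (1088) or from the NCBI gene number in the description matched to the Sscrofa11.1 RefSeq genes (693), and 15867 rows have none. List members were matched by any of these names, so a few rows carry another symbol in the table. Measurement columns that belong to no sample used here number 0. Library totals were 14681221 and 13568525 for Bobcat339 and 14390560 and 13852262 for the control, and 3 counts correspond to 0.204 to 0.221 CPM. Smart-seq2 reads carry no molecular identifiers, so floors and counts cover counting error only. Each library was counted as a separate sample because the labels list it as one. The chi-square per gene was 12.92 for the Bobcat339 pair and 49.93 for the control pair, so neither pair is 1 set of reads deposited again, but repeats of 1 sample could exceed counting noise as well.

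Choices were made before the data were examined unless marked as added. The comparison of Bobcat339 with control used edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 on the group, TMM scaling, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. The filter left 18481 rows, which hold 99.73% of the counts, and removed 16767. Standard errors and 95% intervals come from the fitted log2 fold change and the quasi-likelihood F statistic; printed CPM are TMM-normalised. The common biological coefficient of variation was 26.4%. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 over 26 fixed lists with at least 5 tested members, and again with an estimated correlation and with fry, which asks whether the genes of a set move on balance in 1 direction and does not compare them with other genes. The form with an estimated correlation takes its degrees of freedom from these few libraries. It could therefore hardly pass any list, least of all with a library left out, so a failure there decides nothing. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, no scaling, no filter, at least 5 CPM in 2 libraries, thinning to equal depth, the replicate number as a block, each library left out, an absolute log2 fold change of at least 1, an adjusted p of 0.01, leaving out the 50 most abundant genes, and leaving out mitochondrially encoded genes. Added after the data were seen were DESeq2 with the block, leaving out XLOC loci, removal of a loess trend on gene length (span 0.5, tested with camera on the signed root of F in place of the fitted genes), an estimated correlation with each library left out, lists of metal-responsive and interferon-stimulated genes, and a camera test of 1569 Gene Ontology terms with 15 to 500 tested members as annotated in the table.

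Genes were named by a fixed rule. The first part takes genes with a symbol that pass, that have both Bobcat339 libraries on the same side of both controls and that have a mean of at least 5 CPM; with fewer than 5 passing in a direction, it takes the 5 with the smallest p, here from 1089 higher and 1304 lower genes, none of which passed. The second part takes TET1 to TET3, DNMT1, DNMT3A, DNMT3B and DNMT3L. The third takes up to 4 passing members of each list or, where none pass, the 2 members with the highest mean. The pipeline was tested on simulated data drawn from the means and sizes of these libraries, 2 against 2 with 200 changed genes among 17823 tested. A list of 60 further genes was lowered 2-fold in the same data, and the shares recovered are of the 200 genes. The changed genes were all drawn from those with a mean of at least 5 CPM, so the shares recovered do not cover scarcer genes. The edgeR test recovered 23.9% of genes changed 2-fold, 91% of those changed 4-fold and 100% of those changed 8-fold, with 9 unchanged genes called, and DESeq2 recovered 34.3%, 92.5% and 100% with 11. With the preset correlation the list lowered on purpose had a camera adjusted p of 1.34e-46, and 0 of 20 unchanged lists passed. Those simulated genes vary independently of each other, so the list result does not speak to correlated members. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for the table and figures. Left out of the text are per-gene results for loci without a symbol, and a list member that the naming rule takes is not reported here.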

Results

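Porcine parthenogenetic embryos, which develop from oocytes activated by an electric pulse without sperm, were cultured for 48 h in PZM-3 medium and profiled by RNA sequencing at the 4-cell stage. In 2 samples the medium held 50 µM Bobcat339, a cytosine-based small molecule used as an inhibitor of the TET dioxygenases. These enzymes oxidise 5-methylcytosine in DNA, and RNA libraries do not measure their activity. The other 2 samples received the solvent DMSO and served as the control. The question set by the study's title is how inhibition of TET by Bobcat339 alters gene expression in these embryos. The Bobcat339 libraries held 14681221 and 13568525 counts and the control libraries 14390560 and 13852262. A transcript with 0 counts in a library could therefore have been present at up to 0.204 to 0.221 CPM (counts scaled to the size of the library), the level of 3 counts, a floor that covers counting error only. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

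Abundant transcripts of the 4-cell embryos included the oocyte growth factor BMP15 (4279 CPM over the 4 libraries), the oocyte kinase WEE2 (4160 CPM) and the replication clamp PCNA (4328 CPM). The zygotic transcription factor KLF17 stood at 1186 CPM and the adhesion molecule CDH1 at 1186 CPM. Mitochondrially encoded rows took 4.93% and 4.02% of the counts in Bobcat339 libraries 1 and 2, and 5.59% and 6.36% in control libraries 1 and 2. The Pearson correlation of log2 CPM across genes was 0.976 between the Bobcat339 libraries and 0.959 between the control libraries, the lowest of the 6 pairs. Between the groups it lay between 0.963 and 0.973. The control pair differed by more than 2-fold at 16.2% of genes and the Bobcat339 pair at 8.4%. On the first principal component, with 43.7% of the variance, control 1 (−55.42) and control 2 (41.35) lay at opposite ends with the Bobcat339 libraries (−8 and 22.07) between them.

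No gene passed the edgeR test between Bobcat339 and control embryos, which weighs each difference against the spread between replicates. The genes with the smallest p in the higher direction were SLC30A1, which encodes a zinc exporter of the plasma membrane, GPR50, a melatonin-related receptor, CHST8, a sulfotransferase of N-acetylgalactosamine, HES2, a basic helix-loop-helix factor, and NEFM, a neurofilament subunit. SLC30A1 stood at 111 ± 5.15 CPM in Bobcat339 embryos and 29.7 ± 14.1 CPM in control embryos (SD, n = 2 each). In the lower direction they were GPR85, an orphan receptor, PTTG1 (securin, the inhibitor of separase), the nuclear receptor NR4A2, the LIM homeobox factor LHX5 and PCK1, a key enzyme of gluconeogenesis. PTTG1 stood at 996 ± 55.2 CPM in Bobcat339 embryos and 1923 ± 204 CPM in control embryos (SD, n = 2 each).

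Of 18481 genes tested with edgeR's quasi-likelihood test, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.343. At an unadjusted p under 0.05 there were 740 genes, 252 higher and 488 lower, where chance alone gives 924.1. On the same 18481 genes limma-voom called 0, with 646 at an unadjusted p under 0.05. DESeq2, run on all 30007 rows with a count, called 5 genes, with 558 at an unadjusted p under 0.05. The 5 DESeq2 genes were all higher in Bobcat339 embryos. They were SLC30A1 (DESeq2 adjusted p 0.00147), GPR50 (0.00906), CHST8 (0.0121), HES2 (0.0178) and the chemokine CCL2 (0.0106), which falls outside the naming rule and was chosen after its values were seen. CCL2 was at 1.64 and 11.9 CPM in the Bobcat339 libraries and 0.287 and 0.43 CPM in the control libraries. The 2 groups did not overlap at 5410 genes (29.3%), where chance gives 33.3%. The edgeR count depended on the control libraries: without control 1 it was 586 genes (408 higher, 178 lower) and without control 2 it was 494 (148 higher, 346 lower), the remaining control library being assumed to vary as the Bobcat339 pair did.

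SLC30A1 (ENSSSCG00000039472, chromosome 9: 131632874 to 131641177, plus strand) had a log2 fold change of 1.90 (SE 0.34; 95% interval 1.17 to 2.62; edgeR adjusted p = 0.343), with 1679 and 1470 counts in the Bobcat339 libraries against 554 and 276 in the controls. GPR50 (ENSSSCG00000023462, chromosome X: 122708422 to 122713163, plus strand) had a log2 fold change of 2.02 (SE 0.39) and 68.9 and 197 CPM in the Bobcat339 libraries against 32.0 and 33.4 CPM in the controls. CHST8 (ENSSSCG00000035222, chromosome 6: 43371532 to 43493249, plus strand) had 1.79 (SE 0.36), HES2 (ENSSSCG00000034297, chromosome 6: 67276777 to 67279603, minus strand) 1.87 (SE 0.38) and NEFM (ENSSSCG00000009648, chromosome 14: 8961852 to 8967912, plus strand) 2.02 (SE 0.43) on the same log2 scale. In GPR50, CHST8, HES2 and NEFM the control libraries were close to each other and Bobcat339 library 2 stood above Bobcat339 library 1, with 21.3 against 9.33 CPM for NEFM. GPR85 (ENSSSCG00000016642, chromosome 18: 32667513 to 32672741, plus strand) had a log2 fold change of −1.96 (SE 0.42), with 1.98 and 2.19 CPM in the Bobcat339 libraries against 8.03 and 8.16 CPM in the controls. All 6 genes had an edgeR adjusted p of 0.343. PTTG1 (ENSSSCG00000017032, chromosome 16: 63104778 to 63113151, minus strand) had a log2 fold change of −0.95 (SE 0.22; 95% interval −1.42 to −0.48; edgeR adjusted p = 0.503). NR4A2 (ENSSSCG00000015871, chromosome 15: 63485314 to 63505728, minus strand) had −1.42 (SE 0.35), LHX5 (ENSSSCG00000009869, chromosome 14: 38446730 to 38457177, plus strand) −1.54 (SE 0.39) and PCK1 (ENSSSCG00000007507, chromosome 17: 57930356 to 57938817, plus strand) −1.93 (SE 0.50), with edgeR adjusted p of 0.647, 0.699 and 0.699. The controls of PCK1 were themselves far apart, at 27.8 and 7.66 CPM, and its log2 fold change was −0.72 without control 1 and −2.54 without control 2. Without Bobcat339 2 the log2 fold change of GPR50 was 1.12, of CHST8 1.40, of HES2 1.32, of NEFM 1.36 and of LHX5 −1.08, and that of SLC30A1 was 1.51 without control 2. The coordinates are those of the deposited table, which follow Sscrofa11.1.

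**Figure D1:**
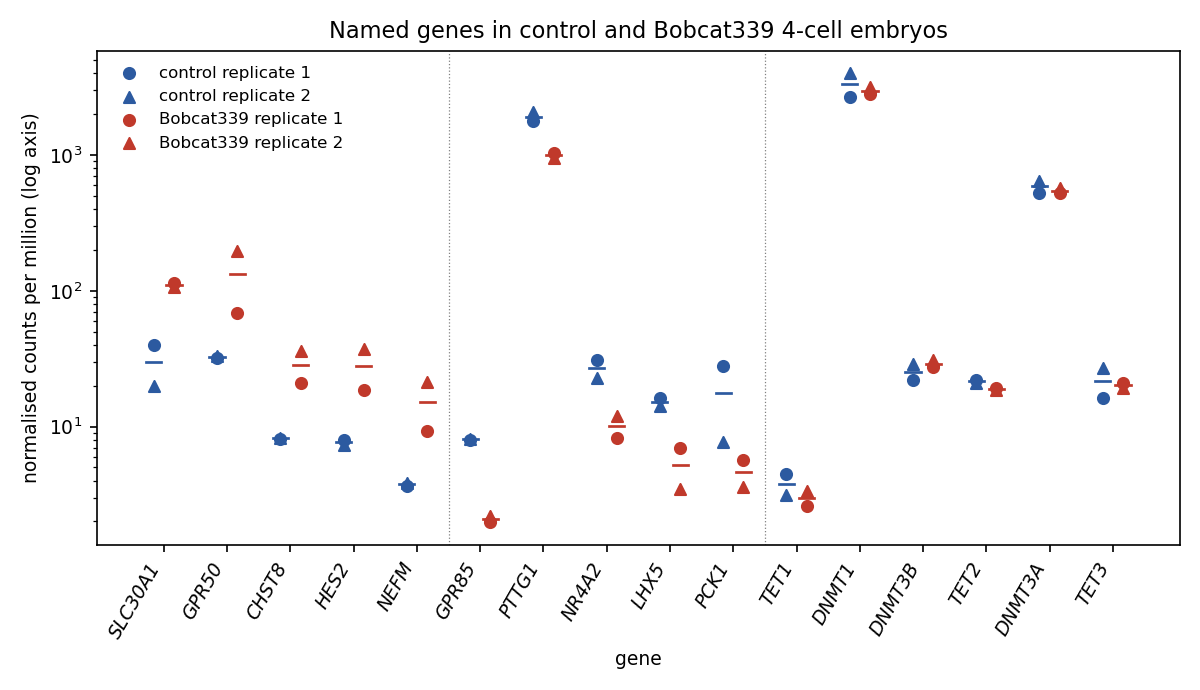
Normalised CPM on a log axis for the 10 genes with the smallest p (5 higher, then 5 lower) and for 6 TET and DNMT genes; each point is a library, circles replicate 1 and triangles replicate 2, and short lines are group means. SLC30A1 lies at 114 and 107 CPM in Bobcat339 against 39.7 and 19.8 CPM in control embryos, and TET2 at 19.3 and 18.6 CPM against 22.1 and 21.0 CPM.

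Neither the transcripts of the inhibitor's targets, the TET enzymes, nor those of the DNA methyltransferases passed the test between the groups. TET3 and TET2 were at 20.9 and 20.2 CPM over the 4 libraries and TET1 at 3.38 CPM, while the maintenance methyltransferase DNMT1 was at 3164 CPM and DNMT3A at 568 CPM. The log2 fold change was −0.35 for TET1 (95% interval −1.31 to 0.60), −0.19 for TET2 (−0.86 to 0.49) and −0.10 for TET3 (−0.82 to 0.63). It was −0.16 for DNMT1 (−0.65 to 0.33), −0.10 for DNMT3A (−0.61 to 0.41) and 0.19 for DNMT3B (−0.48 to 0.87). DNMT3L, a cofactor of the de novo enzymes, had 1 count in control 1 and 0 in the other 3 libraries and was not tested. None of the 6 tested genes passed (edgeR adjusted p = 0.999 each), and the intervals leave room for changes of the widths given. Without control 1, DNMT1 passed at a log2 fold change of −0.43 (edgeR adjusted p = 0.0142), since control 1 had the lowest and control 2 the highest DNMT1 level of the 4 libraries (2665 and 4013 CPM). In the whole list of TET and DNA methylation machinery, 0 of 20 tested members passed over all genes or adjusted over the list alone, and the median log2 fold change was 0.05. The 2 most abundant members were DNMT1 and UHRF2, a reader of hemimethylated DNA (−0.18).

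Members of 3 mitochondrial lists and of the proteasome list mostly had log2 fold changes below 0 in Bobcat339 embryos, but no list passed with a correlation estimated from these data (adjusted p = 0.96 with an estimated correlation), and of these 4 only the mitochondrially encoded list had both Bobcat339 libraries below both controls. All 13 mitochondrially encoded transcripts had a log2 fold change below 0, with a median of −0.43; COX1 (−0.45) and COX2 (−0.46), the catalytic subunits of cytochrome c oxidase, were examples. Of 69 nuclear genes of the respiratory chain 64 were below 0 (median −0.36), of 36 proteasome subunits 31 (median −0.24) and of 27 genes of mitochondrial biogenesis and dynamics 22 (median −0.26). The most abundant members of the last 3 lists were nearer to 0 than the list medians: ATP5B (−0.15) and COX8A (−0.06) of the respiratory chain, PSMD11 (−0.05) and PSMD2 (−0.06) of the proteasome, and the coactivator PPRC1 (−0.05) and the mitochondrial transcription factor TFAM (0.02). With camera at a preset correlation of 0.01 these 4 of the 26 lists passed, all lower: adjusted p = 1.2e-06 for the nuclear respiratory chain, 3.24e-06 for the mitochondrially encoded transcripts, 0.00185 for the proteasome and 0.0345 for mitochondrial biogenesis. None held with the correlation estimated from these data (adjusted p = 0.96 with an estimated correlation, for each of the 4). With fry 0 of 26 lists passed, the adjusted p being 0.983. With 4 libraries the estimated form could hardly pass any list, so its failure does not argue against these shifts. The estimated correlations of the 4 lists, 0.35 to 0.75, lay far above the preset 0.01, so the preset p-values are no firm support either. At an unadjusted p under 0.05 there were 5 lists with the preset correlation, 0 with the estimated correlation and 0 with fry.

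The mitochondrially encoded list was the only one of the 4 in which both Bobcat339 libraries (scores −0.03 and −0.39) lay below both control libraries (0.17 and 0.28), the score being the median over members of log2 CPM minus the gene's mean over the 4 libraries. In the other 3 lists control 1 alone stood high. For the nuclear respiratory chain the scores were 0.46 in control 1, −0.19 in control 2, −0.04 in Bobcat339 1 and −0.25 in Bobcat339 2, and the proteasome had 0.42 in control 1 against −0.18 in control 2. Without control 1 the nuclear respiratory chain (adjusted p = 0.793), the proteasome (0.867) and mitochondrial biogenesis (0.867) no longer passed and the camera direction turned to higher, while the mitochondrially encoded list passed with the preset correlation (2.43e-09; adjusted p = 0.83 with an estimated correlation). Without Bobcat339 2 none of the 4 passed, with adjusted p of 0.197, 0.306, 0.478 and 0.699 for the nuclear chain, the mitochondrially encoded list, the proteasome and mitochondrial biogenesis. Their median log2 fold changes were then −0.18, −0.18, −0.09 and −0.17.

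**Figure D2:**
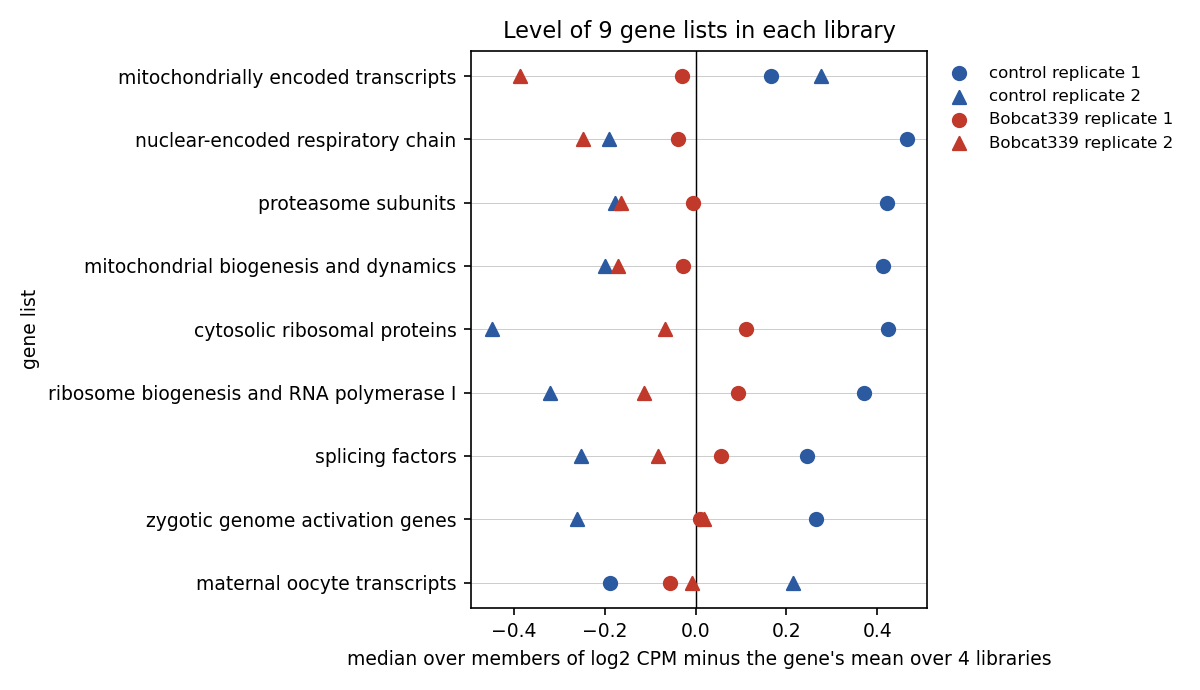
Level of 9 gene lists in each library, as the median over members of log2 CPM minus the gene's mean over the 4 libraries; blue is control, red is Bobcat339, circles replicate 1 and triangles replicate 2. The mitochondrially encoded list has both Bobcat339 libraries (−0.03 and −0.39) below both controls (0.17 and 0.28), while in the other 8 lists a Bobcat339 library lies between the control libraries. Early lineage, cell cycle and pluripotency genes, where the groups are also separated, are not drawn.

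Neither maternal nor zygotic transcripts passed as a group (camera adjusted p = 0.788 and 0.799). The 37 maternal oocyte transcripts had a median log2 fold change of −0.05, with BMP15 at −0.06 and WEE2 at 0.04, and the 26 zygotic genome activation genes a median of 0.01, with KLF17 at −0.04 and the homeobox factor OTX2 at 0.08. The maternal mRNA decay machinery had a median of −0.03 over 37 members, among them the deadenylation adaptor BTG4 (0.27) and the m6A reader YTHDF2 (−0.07). The control libraries differed from each other on the first 2 lists by more than the groups did: control 1 lay 0.53 above control 2 (log2) in zygotic genes, and the same difference was −0.40 in maternal transcripts. Without control 1 the zygotic list was higher in Bobcat339 embryos (median log2 fold change 0.27) and the maternal list lower (−0.25), both at a camera adjusted p of 0.00167 with the preset correlation (adjusted p = 0.83 with an estimated correlation). Without control 2 the medians had the other sign, −0.20 for the zygotic and 0.10 for the maternal list, and neither passed (camera adjusted p = 0.129 and 0.0692). Pluripotency genes had a median of −0.12 (TFAP2C −0.16, MYC 0.22; 15 of 20 below 0). Early lineage genes had the highest median of the 26 lists, 0.15 with 16 of 25 above 0 (CDH1 0.05, the Hippo effector YAP1 0.12), and a camera adjusted p of 0.0694 (adjusted p = 0.96 with an estimated correlation). Imprinted genes had a median of 0.11 over 16 members, with MEST at 0.15 and NAP1L4 at −0.04. Histone modifiers had a median of −0.09 over 48 members, with the demethylase KDM5A at −0.03 and ASH2L, a subunit of histone methyltransferase complexes, at 0.00.

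Cell cycle genes had a median log2 fold change of −0.06 over 55 members, and PTTG1 was the only member of any list that passed when adjusted over the list alone (edgeR, Benjamini-Hochberg adjusted p = 0.03), although it did not pass over all genes. PCNA, the most abundant member, was at 0.06. Apoptosis genes had a median of −0.02 (BCL2L1 0.03, MCL1 −0.07), p53 targets and DNA damage genes −0.05 (PPM1D 0.27, CCNG1 −0.30), antioxidant genes 0.03 (PRDX2 −0.61, TXNRD1 −0.23) and autophagy genes −0.01 (ATG4A −0.10, GABARAPL2 0.04). The unfolded protein response had a median of 0.11 (PDIA4 0.11, MANF −0.02) and heat shock genes −0.12 (HSPA8 −0.06, DNAJB1 0.22). Cytosolic ribosomal proteins had a median of −0.02 over 79 members (RPLP1 0.21, RPLP0 0.02), ribosome biogenesis −0.11 (NPM1 0.15, NCL 0.32) and splicing factors −0.03 (SRSF1 0.15, HNRNPA2B1 0.12). Glycolysis and glucose uptake had a median of 0.08 (PDHA1 −0.05, HK2 0.20) and lipid genes −0.11 (ACSL3 0.37, FDFT1 −0.10). Within these lists 0 members passed over all genes by edgeR, and the adjusted p of the list by camera lay between 0.289 for the unfolded protein response and 0.992 for autophagy. The camera direction was higher although the median was below 0 for apoptosis genes, ribosomal proteins, p53 targets and lipid genes, and higher with a mean below 0 for zygotic genes. Control 1 and control 2 lay at opposite ends in ribosomal proteins (0.42 and −0.45), so that this list passed as higher without control 1 (adjusted p = 1.68e-19) and as lower without control 2 (8.99e-09), with the preset correlation; adjusted p = 0.83 and 0.775 with an estimated correlation.

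Markers of other cell types did not pass as groups. Cumulus and granulosa cell markers had a median log2 fold change of −0.13 over 17 tested members (camera adjusted p = 0.603), with the matrix proteoglycan VCAN at 72.0 CPM (0.09) and VIM at 39.8 CPM (0.08). Their score was −0.34 in Bobcat339 1, 0.23 in Bobcat339 2, −0.03 in control 1 and 0.19 in control 2, and the list passed as lower without Bobcat339 2 (adjusted p = 0.00741; adjusted p = 0.995 with an estimated correlation). Of the blood and immune cell markers 7 were tested, with a median of −0.17 (camera adjusted p = 0.951), and the most abundant was CD74 at 4.75 CPM (0.74).

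**Figure D3:**
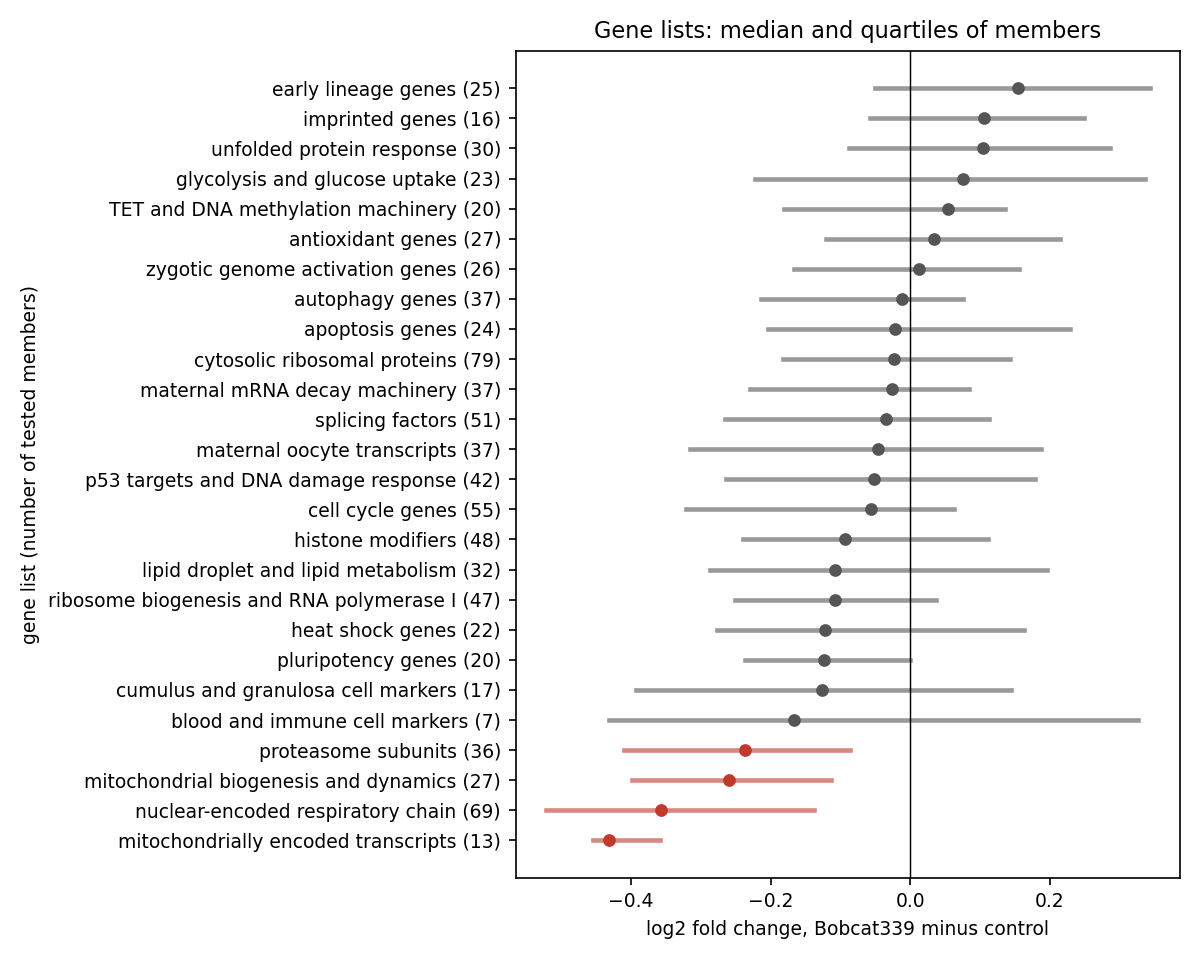
Median (point) and quartiles (bar) of the log2 fold change of Bobcat339 minus control over the tested members of each of 26 gene lists; red marks the 4 lists past a camera adjusted p of 0.05 with the preset correlation. The red lists have medians from −0.43 to −0.24, and none of them passes with an estimated correlation (adjusted p = 0.96), a form that could hardly pass any list with so few libraries.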

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

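DESeq2 with the block, the removal of XLOC loci, the removal of the gene length trend and the estimated correlation with a library left out were tests chosen after the results were seen. The edgeR count of genes stayed at 0 under both other scalings, both other filters, thinning, without the 50 most abundant, mitochondrially encoded or XLOC genes and with limma-voom; DESeq2 gave 5. An absolute log2 fold change of at least 1 or an adjusted p of 0.01 could only leave it at 0. Leaving out each library gave 0 to 586 genes, 0 to 1 TET or DNMT genes, 1 to 8 lists and for the similarity of the libraries, as correlation within minus between groups, −0.0104 to 0.0061 (−4e-04 with all 4); the lone library is assumed to vary like the other pair. The labels do not pair the samples, there are only 2 pairs, and what same-numbered libraries share is not known. Their deviations correlated at 0.159 across genes. Grouping the libraries by that number gave 1828 genes at an unadjusted edgeR p under 0.05, against 740 for the treatment. The fit with a replicate block gave 44 genes (23 higher, 21 lower), among them 9 of the 10 genes named by smallest p (all but PTTG1), MT1A and USP18. DESeq2 with the block gave 6, all higher. These calls rest on a pairing that the labels do not give. Of the 26 lists 4 passed, against 0 with an estimated correlation (0.96 for each of the 4) and 0 with fry (0.983). Without mitochondrially encoded genes 2 passed, and the mitochondrially encoded list could not be tested there. Without the 50 most abundant genes that list was not tested either. With camera at the preset correlation, mitochondrial biogenesis had an adjusted p of 0.0627 without mitochondrially encoded genes and 0.0518 without XLOC loci. Early lineage genes passed in that test at 5 CPM (0.0298), thinned (0.0408), without XLOC loci (0.0421) and with the length trend removed (0.0288). In the last case the changed form of the test and not the trend made the call, since that form gave 0.0345 before removal. With an estimated correlation early lineage genes had an adjusted p of 0.96 in the main fit. That form has so few residual degrees of freedom, fewest with a library left out, that it could hardly pass any list. Its failures below are therefore no evidence on the lists. With each library left out, 0 lists passed with an estimated correlation, and the adjusted p with the preset correlation ranged as follows: zygotic genome activation genes 0.00167 to 0.881, maternal oocyte transcripts 0.00167 to 0.985, early lineage genes 0.0293 to 0.478, nuclear-encoded respiratory chain 3.63e-18 to 0.793, mitochondrially encoded transcripts 2.43e-09 to 0.306, mitochondrial biogenesis and dynamics 3.38e-05 to 0.867, unfolded protein response 4.58e-05 to 0.873, cytosolic ribosomal proteins 1.68e-19 to 0.532, ribosome biogenesis and RNA polymerase I 1.98e-05 to 0.478, splicing factors 0.000173 to 0.699, proteasome subunits 1.8e-09 to 0.867, glycolysis and glucose uptake 0.00616 to 0.985, cumulus and granulosa cell markers 0.00741 to 0.977. Without control 1 the direction turned for the nuclear respiratory chain (0.793), mitochondrial biogenesis (0.867), the proteasome (0.867), ribosome biogenesis (2.97e-05) and splicing factors (0.000655), and without control 2 for ribosomal proteins (8.99e-09), because control 1 lies above the other 3 libraries in these lists and control 2 below them in ribosomal proteins; the cause of the other changes was not tested. Of 66 named genes 42 changed sign under at least 1 setting and 19 passed under some setting. None of the 42 was among the 10 with the smallest p. The naming rule required those 10 to have both Bobcat339 libraries on the same side of both controls. Leaving out a library could thus hardly turn their sign. Of the 26 lists 21 changed direction under some setting. With 2 libraries per group, edgeR recovered 23.9% of simulated 2-fold changes in genes of at least 5 CPM. A change of that size or smaller could thus often be missed at this replication. At 4-fold edgeR recovered 91% of the simulated changes, so some of that size could be missed too. GPR85, near 4-fold (log2 fold change −1.96) with close replicates, did not pass (edgeR adjusted p = 0.343). Whether its difference is real is not known, so it does not show a missed change.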

Other observations

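The Gene Ontology test, the tests of the control libraries' timing, of maternal turnover, of gene length and of cumulus cells, and the choice of the metal and interferon lists were made after the gene results were seen, as were the tests of the mitochondrially encoded list apart from the other lists. A first test of that list against each control alone, which had argued against the timing of the controls, restated the separation the list was singled out for and was replaced by the gap between libraries. A slower turnover of maternal transcripts in Bobcat339 embryos was considered first and was set aside, after its values were seen (maternal median −0.05, zygotic median 0.01), for the timing of the controls. Of 1569 terms, camera with the preset correlation put 19 lower and 4 higher past an adjusted p of 0.05, and 0 passed with an estimated correlation (adjusted p = 0.998). With so few libraries that form could hardly pass any term. Lower were respiratory chain complex I (43 genes, median log2 fold change −0.38, adjusted p = 0.00064), DNA replication (77 genes, −0.21, 0.0161), the large subunit of the mitochondrial ribosome (44 genes, −0.28) and aminoacyl-tRNA ligases (38 genes, −0.25). Higher were semaphorin receptor binding (17 genes, 0.27, adjusted p = 0.0285) and chemorepellent activity (20 genes, 0.26). Among single genes chosen after their values were seen, the catalytic subunit of DNA polymerase delta POLD1 (−1.23), the helicase subunit MCM5 (−0.84), the transferrin receptor TFRC (−1.21), the pluripotency factor SOX2 (−0.90) and the oocyte importin KPNA7 (−0.77) were lower in both Bobcat339 libraries than in both controls, none of them past the edgeR threshold (adjusted p = 0.789 for TFRC and higher for the others). The other 2 ways of splitting the 4 libraries in pairs gave 100 and 12 Gene Ontology terms against 23 for the real split with the preset correlation, and all 3 splits gave 0 with an estimated correlation. In single genes the split by replicate number gave 1 gene by edgeR, 44 by DESeq2 and 1828 at an unadjusted edgeR p under 0.05, and the remaining split 0, 0 and 410, against 0, 5 and 740 for the real split. The split by replicate number thus points to a structure of the samples apart from the treatment, and 3 splits are too few for a share under 0.05.

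Transcripts of several imprinted genes that are expressed from the paternal copy in other mammals were present in these embryos, which have no paternal genome. The counts do not tell RNA stored in the oocyte from RNA made in the embryo. MEST had 2292 to 2764 counts per library, PEG10 915 to 1150 and SNRPN 716 to 1014, whereas PEG3 had 4 to 9 and DLK1 0 to 1. Rows placed on chromosome Y took 0.0179% to 0.0203% of the counts in embryos that cannot carry a Y. Among named rows there, PNPLA4 had 175 to 314 counts and STS 39 to 64, both genes that are X-linked in humans.

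The first pattern is the lower level of the mitochondrial and proteasome lists in Bobcat339 embryos, for which TET inhibition is a candidate explanation, set here against 3 others. With the preset correlation the other 2 splits of the 4 libraries gave 9 and 12 lists against 4 for the real split, the highest other being 12, and with an estimated correlation all 3 splits gave 0; the counts point to a structure of the samples apart from the treatment, and 3 splits are too few for a share under 0.05. The nuclear respiratory chain (medians −0.48 and −0.27 in the other splits, −0.36 in the real one) and the proteasome (−0.44 and −0.20, against −0.24) follow that structure. Both passed in both other splits with the preset correlation. Mitochondrial biogenesis passed in the split by replicate number but not in the remaining split. The mitochondrially encoded list had medians of −0.056 and 0.204 against −0.431. It also passed in the remaining split, which leaves this structure open for that list. A trend with the deposited gene length is argued against as the whole cause. After its removal the called list nearest to 0, the proteasome, kept a median of −0.185. That length is of unstated origin, and for RPLP1 (5231 bases) it exceeds the locus itself (chromosome 1: 167296075 to 167300229). A trend with mRNA length was therefore not tested. Controls at different points of the maternal to zygotic transition could contribute to the nuclear chain, proteasome and biogenesis lists, since control 1 minus control 2 was 0.526 in the zygotic and −0.402 in the maternal list and none of the 3 passed without control 1, and this stays open for the mitochondrially encoded list too, where the lower control exceeded the higher Bobcat339 library by 0.197 while the Bobcat339 libraries differed by 0.355, and whose median was −0.176 without Bobcat339 2.

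The second pattern is the higher level of SLC30A1 (log2 fold change 1.90) and of the metallothionein MT1A (2.18; 93 and 70 counts against 15 and 20), both known targets of the metal-responsive transcription factor, where MT1A was chosen after its values were seen and neither passed the edgeR test. A general response to metal ions could not be decided by the other 5 tested metal-responsive genes, too few of which were abundant. Their median was −0.002 (SD over genes 0.48), from −0.49 for SLC30A2 to 0.83 for the scarce MT3 (10 and 26 counts against 3 and 17). The log2 fold changes of MT3, MT1D (0.18, at 2.33 CPM) and SLC30A10 (−0.002, at 3.15 CPM) had SE of 0.799, 0.573 and 0.465. The abundant metallothionein MT1X, at 257 CPM, was at −0.07 (SE 0.279) and did not share the rise. Cumulus cells carried into the Bobcat339 libraries are argued against by the 17 markers, with a median of −0.126 (SD over genes 0.71) and with VCAN and VIM at 0.09 and 0.08. The rule that sets these medians against the spread of the members was written after the medians were seen. It left each verdict as it was under the earlier rule. For metal ions both rules spoke against the explanation, a verdict not kept here because of the scarce genes. An effect of Bobcat339 on these 2 genes stays open as a hypothesis, as does a response to metal ions. Reads shared within the metallothionein family stay open for MT1A too and were not tested.

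The third pattern is the higher level of USP18, an interferon-induced deubiquitinase (log2 fold change 2.11; 171 and 341 counts against 85 and 33), chosen after its values were seen and not past the edgeR threshold (adjusted p = 0.343). A general interferon response is argued against, since the other 19 tested interferon-stimulated genes had a median of −0.042 (SD over genes 0.36), with MX1 at −0.09 and IFIT5 at 0.40. The highest values among them were ISG15 at 0.94 (11 and 79 counts against 24 and 23) and OAS2 at 0.57 (49 and 121 against 53 and 61), both highest in Bobcat339 2, where USP18 was highest too. The control libraries were at 6.09 and 2.36 CPM and the Bobcat339 libraries at 11.6 and 24.8 CPM, and an effect of Bobcat339 stays open and untested.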
